A study of Mus musculus with 2 samples.

How the data were processed

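Single-cell 3′ RNA libraries (10x Chromium, version 3 chemistry, read on a NovaSeq 6000) were made from bone marrow cells enriched with CD117 MicroBeads, with 1 library of KrasG12D/+ and 1 of WT mice, both labelled as the same batch. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization, per the file headers. The matrix headers name Cell Ranger 4.0.0, whereas the submitters' processing notes name Cell Ranger 2.1.1 and the builds mm10 and GRCm38. The number of mice per library, the annotation release, the counting of introns and the calling of barcodes are not given in the sources used here. No barcode had under 500 UMIs in either matrix. All 55450 gene identifiers of the matrices were found in the GENCODE M21 annotation of GRCm38, which gave the coordinates (counted from 1) and transcript lengths. Newer names of ATP synthase genes were absent and the older ones were used.

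The KrasG12D/+ matrix held 7993 barcodes and 131569918 UMIs, and the WT matrix 8649 barcodes and 125315503 UMIs. Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs, which removed 4.18% and 8.41% of the barcodes. Doublets were scored per library with a Scrublet procedure at an expected rate of 6%. The automatic threshold failed in the KrasG12D/+ library, where it marked 0.0131% of the cells at a score of 0.639, so the WT threshold of 0.248 was used for both. It removed 244 cells (3.19%) and 251 cells (3.17%) and left 7415 and 7671. The median mitochondrial share was 0.380% and 0.572%. The 10 most abundant genes took 25.5% of the KrasG12D/+ and 17.0% of the WT UMIs, haemoglobin genes 0.139% and 0.413%, and ribosomal protein genes 18.8% and 18.9%.

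Counts per cell were scaled to 10000 UMIs and log-transformed. Both libraries were clustered together without integration, on 2000 variable genes chosen within each library among genes in at least 10 cells, with 30 principal components, 15 neighbours and Leiden clustering at resolution 1. Sex-linked, mitochondrial and ribosomal protein genes were left out of the variable genes. The 28 clusters were named from marker lists, by the markers among a cluster's 10 leading genes (with 10 CPM added). A name also required at least 3 markers at 2-fold with at least 10 UMIs. This gave 15 classes and 1 unnamed cluster. Class names mean likeness to a cell type. The lymphoid progenitor-like cluster had as many dendritic as lymphoid markers among its leading genes, and the basophil/mast-like cluster was also led by the eosinophil genes Epx and Prg3.

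Gene levels were UMIs summed over the kept cells of a library or class and scaled to its total (CPM). Levels have exact Poisson, ratios exact conditional binomial and shares exact Clopper-Pearson 95% intervals; these cover counting error only. A gene counted as measured with at least 100 UMIs over both libraries in the cells compared and at least 20 CPM in 1 of them. A gene counted as higher or lower at 1.5-fold or more with an interval of the ratio that excluded 1. A gene at 0 UMIs is given against a floor of 3 counts of its class or library total, also as the upper limit of its level, and entered list medians at that bound. No test between genotypes was run and no count of changed genes over the genome is given, because there was 1 library per genotype and cells are not replicates.

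The genes named were set by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest ratios in whole libraries, the 6 highest and 6 lowest in each class with at least 100 cells per library, the 8 genes each way with the largest smallest change over at least 3 classes, 2 members each way of each fixed list, and Kras, Nras, Hras and Kit. Genes with clone or predicted names, mitochondrial, ribosomal protein, sex-linked and antigen receptor segment genes were left out of the rankings. Fn1 in monocyte-like, BC100530 in maturing neutrophil-like and Fbp1 in neutrophil progenitor-like cells met the rule but lead their own clusters, so they are not given as results within those classes. Stat1, Isg15, B2m, Jun, Gata1, Tfrc, Mki67 and S100a8 stand outside the rule and were chosen from the fixed lists after their values were seen, as were Cirbp and Rbm3 beyond the 6 classes and the genes of the closing observations. Classes with at least 50 cells per library (HSC/MPP-like, B lineage-like, T/NK-like and dendritic-like) were added after the data were examined, which made 10 classes. A total of 25 gene lists and the marker lists were fixed before the data were examined; ribosomal protein and mitochondrial genes were taken by name. Each list's median log2 ratio was set against 10000 random lists of the same size matched on expression in 20 bins.

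Cell cycle phases were called from the S and G2/M lists with every cell thinned to 6500 UMIs, which left out 1008 and 1895 cells with fewer. Diffusion pseudotime used 15 components and a root among HSC/MPP-like cells. Recovery was tested on simulated data with 200 genes changed by 0.25, 0.5, 2 or 4-fold: in whole libraries all 50 genes of each size were recovered, and in a class of about 1% of the cells 34 of 34, 36 of 36, 49 of 50 and 50 of 50 of those over the floor. In that class 3052 of 3083 unchanged genes (99.0%) stayed under the threshold. The simulated counts held Poisson error around a shared mean, without variation between cells, class mixes or animals. These rates therefore cover counting error only and are no error rate for the real libraries.

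Alternatives fixed beforehand were TMM and median-of-ratios scaling, the mean of per-cell CPM, weighting to the WT class shares, totals without haemoglobin, mitochondrial and ribosomal genes, no floor, no filter, a stricter filter (at least 1000 genes and at most 5% mitochondrial UMIs), doublets kept, resolutions of 0.5 and 2, 15 principal components, other roots, cell cycle genes left out, classes from the WT cells alone and thinned cells. Added later were clustering without 118 genes that differ between the libraries at 2-fold in all classes or belong to 3 lists, and shares counted without the neutrophil, monocyte, dendritic and unnamed cells, and list medians taken from genes matched on transcript length (10 bins) and expression (5 bins). The interval of the difference between interferon gene groups came from bootstrap draws of their genes, and intervals of medians over genes from ranks; both cover the spread of genes. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. R 4.3.3 with edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (median of ratios) gave scale factors only. The random seed was 1.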

Results

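Single-cell RNA profiles were collected from the marrow of mice aged 6 weeks, from cells enriched with CD117 (c-Kit) beads for haematopoietic stem and progenitor cells. The selected cells also included mature types, as the classes below show. The genotypes were KrasG12D/+, a model of juvenile myelomonocytic leukaemia, and wild type (WT). The comparison asks which cell types and genes differ between these genotypes. There was 1 library per genotype and no replicate, so no test between genotypes was run. Unless stated otherwise, every interval of a share, level or ratio is an exact 95% interval that covers counting error only. The words "higher" or "lower" without a number mean at least 1.5-fold by the level in the KrasG12D/+ library over that in WT. The KrasG12D/+ library gave 7415 kept cells with 124532079 UMIs in all and a median of 16315 UMIs and 2953 genes per cell. The WT library gave 7671 kept cells with 117686040 UMIs and a median of 12513 UMIs and 2963 genes per cell.

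The KrasG12D/+ library held more dendritic-like cells and, in most settings, neutrophil progenitor-like cells. It held fewer HSC/MPP-like (stem and multipotent progenitor), megakaryocyte-like, early erythroid-like, B lineage-like and macrophage-like cells. Dendritic-like cells, antigen-presenting cells led by MHC class II genes, made up 9.24% [8.59 to 9.92] of the KrasG12D/+ cells and 1.03% [0.816 to 1.28] of the WT cells, a ratio of 8.97 [7.10 to 11.5]. With classes from WT alone this ratio was 4.01 [3.43 to 4.70], from 783 against 202 cells. HSC/MPP-like cells made up 0.755% [0.571 to 0.980] against 5.68% [5.18 to 6.23], which was 7.53-fold lower (ratio 0.133 [0.0987 to 0.176]). Their ratio was 0.204 with the stricter filter, 0.192 at resolution 2 and 0.181 without cell cycle genes. Early erythroid-like cells, the red cell precursors, made up 3.78% [3.35 to 4.24] against 12.9% [12.2 to 13.7], which was 3.43-fold lower.

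Among the other lineages, megakaryocyte-like cells, which make platelets, stood at 0.486% against 2.85% (ratio 0.170 [0.116 to 0.243]; 0.105 with classes from WT alone, 0.0666 with the stricter filter and 0.0396 when thinned). B lineage-like cells stood at 1.23% against 4.38% (ratio 0.280 [0.220 to 0.354]) and macrophage-like cells at 0.634% against 3.23% (ratio 0.196 [0.140 to 0.269]). Late erythroid-like cells had a ratio of 0.408 [0.274 to 0.596], and of 1.02 [0.683 to 1.49] counted without the neutrophil, monocyte and dendritic classes. Without the filter on cells their ratio was 0.234 [0.166 to 0.323], from 46 against 213 cells. Plasma cell-like cells had a ratio of 0.148 [0.0513 to 0.349], from 6 cells against 42, and of 0.752 [0.620 to 0.912] without the filter on cells, from 184 against 265. Neutrophil progenitor-like cells stood at 27.1% [26.1 to 28.1] against 17.2% [16.4 to 18.1], a ratio of 1.57 [1.47 to 1.69], which fell under 1.5 with the stricter filter (1.23) and without cell cycle genes (1.32). Maturing neutrophil-like cells were the most numerous class in both libraries, at 36.1% and 33.5% (ratio 1.08 [1.02 to 1.14]), and monocyte-like cells stood at 12.1% and 8.98% (ratio 1.35 [1.22 to 1.49], turned to 0.899 [0.804 to 1.01] at resolution 2). Lymphoid progenitor-like cells had a ratio of 1.69 [1.41 to 2.04], a direction that 3 other settings reversed, with ratios of 0.744, 0.817 and 0.854. In 2 more settings (0.150 and 0.246) the cluster of that name scored best for HSC/MPP, a class those settings did not name. The intervals of the ratios of T/NK-like (1.05), basophil/mast-like (1.16) and stroma/endothelium-like cells (0.690) included 1. These ratios depend on the setting: T/NK-like cells stood at 0.479 [0.249 to 0.889] when thinned, stroma/endothelium-like cells at 0.664 [0.455 to 0.959] without the filter, and basophil/mast-like cells at 0.475 [0.389 to 0.579] at the coarser clustering, where their cluster scored best for megakaryocytes. A cluster led by Il1b, Cxcl2, Acod1 and Ptgs2, genes of inflammatory activation, held 0.971% of the KrasG12D/+ and 3.01% of the WT cells. It was left without a name because no marker stood among its 10 leading genes, though it scored best for maturing neutrophils.

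**Figure D1:**
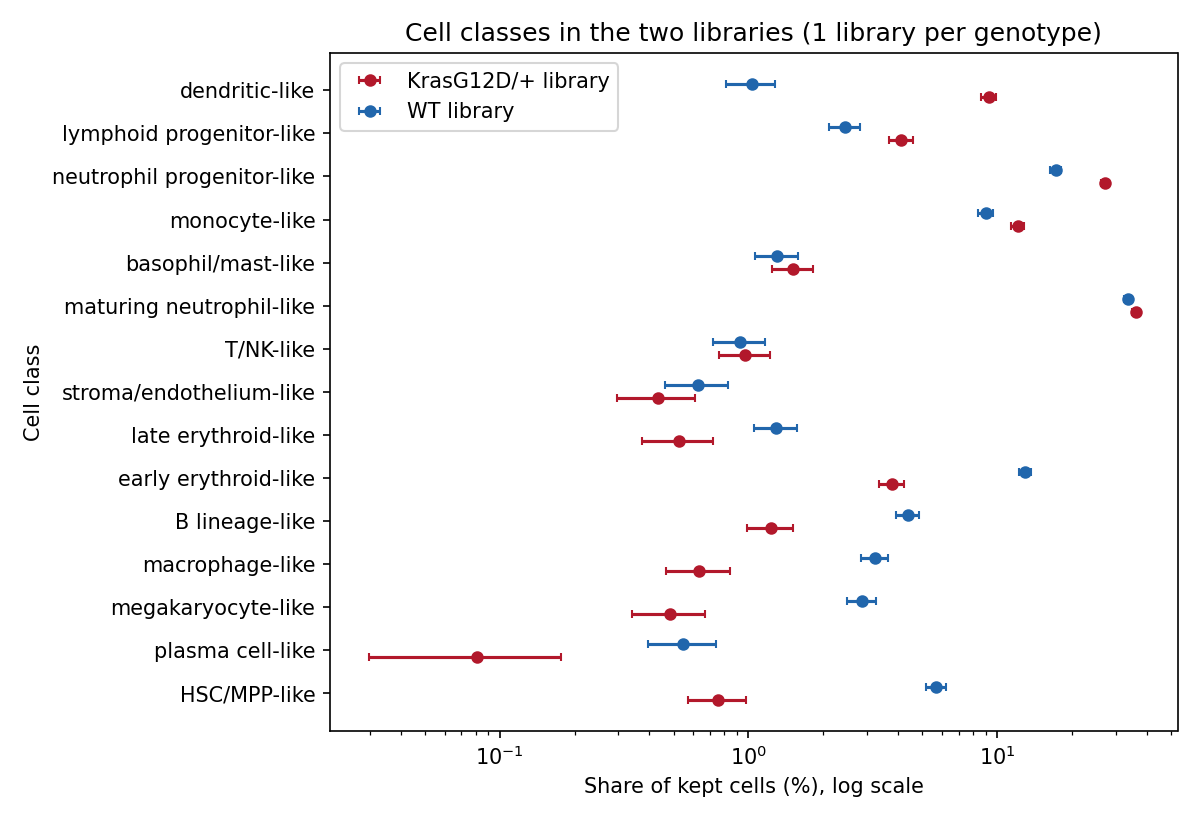
Share of kept cells (%, log scale) in each cell class of the KrasG12D/+ library and the WT library, with exact 95% binomial intervals; 1 library per genotype. Dendritic-like cells stand at 9.24% against 1.03%, and HSC/MPP-like cells at 0.755% against 5.68%.

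These shares describe cells taken with CD117 beads, so they also depend on how pure each selection was. Kit, the bead target, stood at 31.8 CPM (UMIs scaled to the library total) in the whole KrasG12D/+ library and 54.9 CPM in WT, a ratio of 0.578 [0.556 to 0.602] (0.782 with TMM), and at 97.49 against 166 CPM in HSC/MPP-like cells. With cells thinned to 6500 UMIs the early erythroid-like ratio was 0.353. The thinned dendritic-like class (ratio 2.22) pooled the cluster led by MHC class II genes (538 against 66 cells) with one that scored best for lymphoid progenitors (191 against 230). The thinned macrophage-like class (ratio 2.40) held other cells than the one above, whose cells had a median of 1239 UMIs, and was led by Fn1 and S100a4 beside C1q genes (88 against 33). At the coarser clustering the class named dendritic (ratio 1.49) pooled the cluster led by MHC class II genes (812 against 112) with one that scored best for HSC/MPP (223 against 608). HSC/MPP-like and megakaryocyte-like ratios counted without the neutrophil, monocyte and dendritic classes were 0.331 and 0.424, and early erythroid-like and B lineage-like ratios counted that way were 0.728 and 0.699. The T/NK-like, basophil/mast-like and stroma/endothelium-like ratios counted that way were 2.62 [1.86 to 3.68], 2.89 [2.19 to 3.82] and 1.72 [1.06 to 2.75].

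Kras (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239, GRCm38) stood at 76.2 CPM in the KrasG12D/+ library and 68.9 CPM in WT, a ratio of 1.11 [1.07 to 1.14]. Counts from transcript 3′ ends do not read the G12D change, so this level does not check the labels. Nras, another Ras gene, was lower than in WT at 45.6 against 70.8 CPM (ratio 0.645 [0.623 to 0.667]; 0.872 with TMM and 0.855 with median of ratios, short of 1.5-fold), and its ratio lay between 0.523 and 0.803 in the 10 classes, in T/NK-like cells from counts below the floor. Hras stood at 52.2 against 67.8 CPM (ratio 0.770 [0.745 to 0.796]), and this direction turned with TMM scaling (1.04) and with median-of-ratios scaling (1.02). Both libraries carried Y-linked transcripts, with Ddx3y at 32.6 and 48.7 CPM and Eif2s3y at 58.9 and 50.02 CPM, and Xist had 14 and 12 UMIs.

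Interferon-induced genes were the lowest genes of the KrasG12D/+ library. Iigp1, an interferon-inducible GTPase of pathogen defence (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634), stood at 0.602 CPM against 236 CPM in WT, 391-fold lower. Gbp2, a guanylate-binding protein of the same defence (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008), stood at 1.28 against 154 CPM, 120-fold lower. Among the 10 lowest genes were also Serpina3f (136-fold lower), Ifi44 (42.3-fold), Gbp5 (42.0-fold), Oasl2 (34.7-fold), Irgm2 (32.9-fold), Igtp (32.5-fold), Serpina3g (28.9-fold) and Ly6a (24.0-fold), which encodes the stem cell antigen Sca-1. Irgm2 overlaps Igtp on chromosome 11, and Serpina3f and Serpina3g are near-identical, so the counts of these pairs are not fully separate.

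The fixed interferon response list was lower in all of its 19 measured members, also with TMM scaling. Its median log2 ratio lay -2.99 from the all-gene median, below all 10000 random lists matched on expression. The all-gene median itself lay at -0.40 with library totals as scale, at 0.07 with TMM and at 0.03 with median of ratios. List medians are given relative to it. Counts of higher or lower members with library totals include this shift of all genes, so they are read beside the counts with TMM. Stat1, the transcription factor of the interferon response, stood at 22.6 against 238 CPM (10.5-fold lower) and Isg15 at 2.70 against 55.1 CPM (20.4-fold lower). The least lowered members were Ifi27l2a (3.21-fold) and Ifitm3 (2.81-fold). Of 14 MHC class I genes, which present peptides to CD8 T cells, 13 were lower (12 with TMM), with a list median of -1.64. H2-Q7 (ENSMUSG00000060550, chromosome 17, 35439155 to 35443773), which is near-identical to H2-Q6, was 23.7-fold lower, Nlrc5, the activator of class I genes, was 18.7-fold lower, and B2m, the shared light chain, was 3.80-fold lower at 629 against 2387 CPM.

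This pattern held within the cell classes. All measured interferon members were lower in 8 of the 10 classes, with list medians from -2.63 in B lineage-like to -4.59 in neutrophil progenitor-like cells. In dendritic-like cells 13 of 14 were lower (9 with TMM; median -0.86), and in T/NK-like cells 5 of 6 were lower and 1 was higher (median -1.33). MHC class I medians ran from -0.84 in dendritic-like to -2.52 in early erythroid-like cells. In early erythroid-like cells Gbp2 had 1 UMI in KrasG12D/+ against 265 CPM in WT, a ratio of 0.000466 [1.18e-05 to 0.0026], and Iigp1 had 0 UMIs against 540 CPM, at least 1457-fold lower against a floor of 3 counts. Iigp1 also had 0 UMIs in KrasG12D/+ monocyte-like cells (at least 1127-fold lower) and neutrophil progenitor-like cells (at least 1010-fold lower). In HSC/MPP-like cells Iigp1 was 62.7-fold lower, at 7.57 against 474 CPM. Of the genes over the floor in several of the 6 classes with at least 100 cells per library, Gbp2 was lower by no less than 13.3-fold in 6 classes, H2-Q7 by 9.99-fold in 6, Oasl2 by 11.1-fold in 5 and Ly6a by 37.9-fold in 3.

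**Figure D2:**
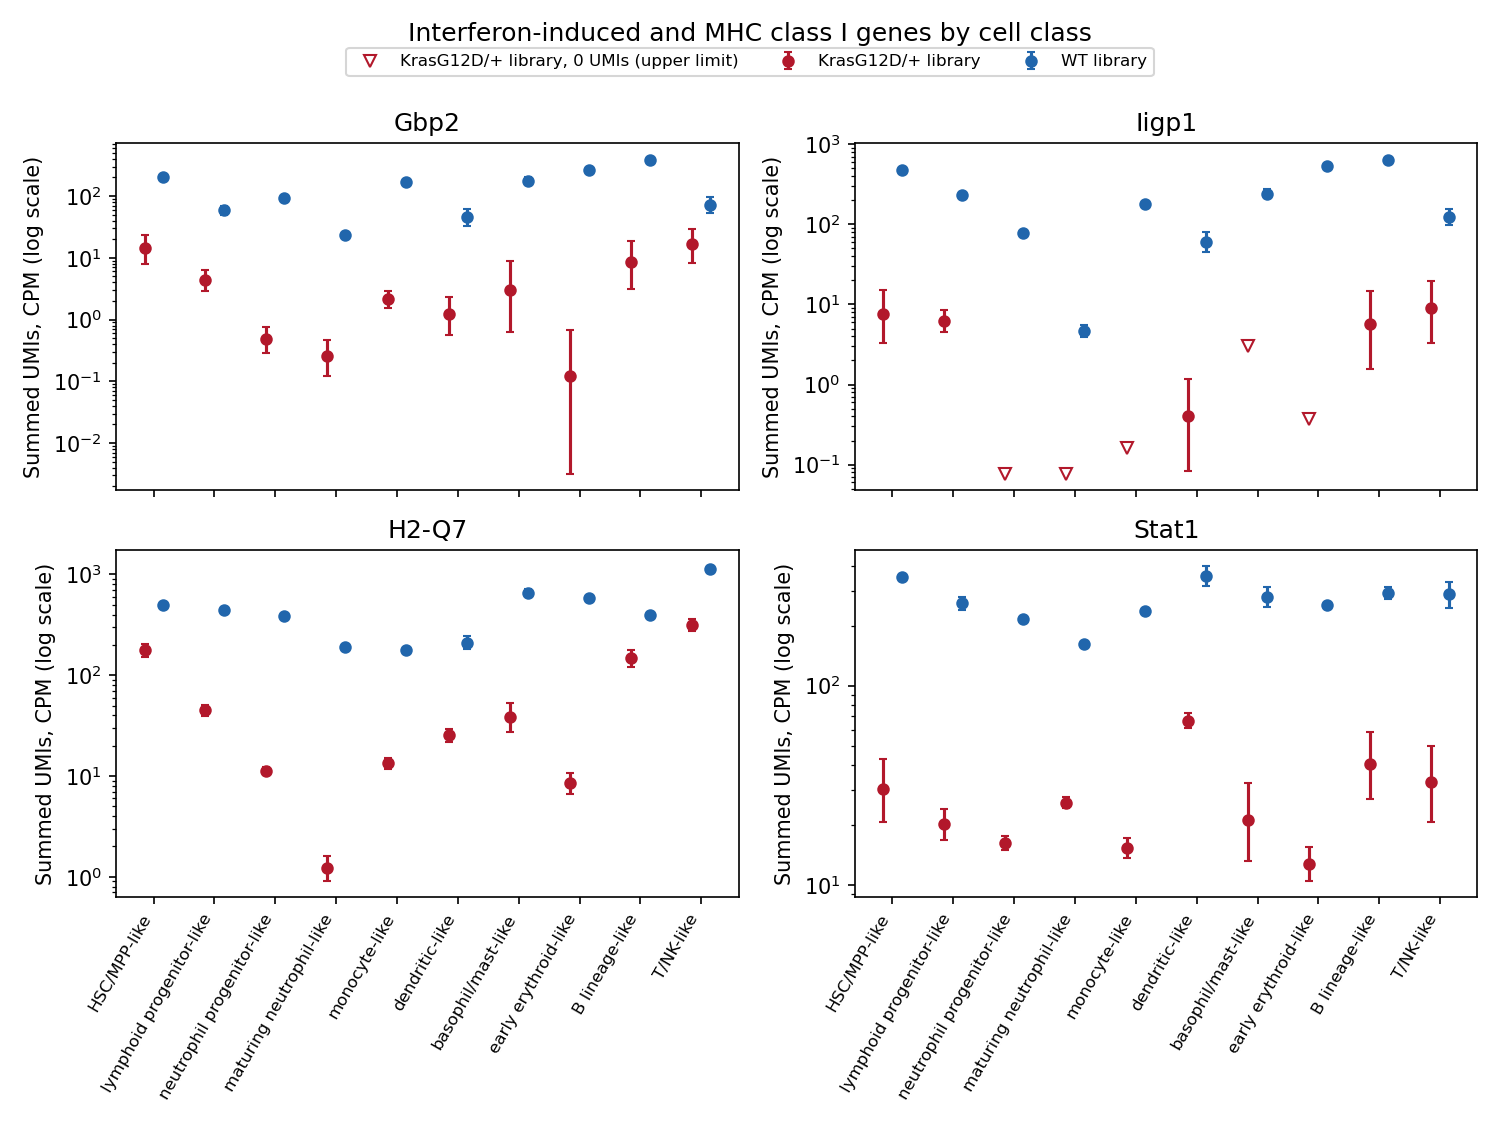
Levels of Gbp2, Iigp1, H2-Q7 and Stat1 (summed UMIs as CPM, log scale) in 10 cell classes of the KrasG12D/+ library and the WT library, with exact 95% Poisson intervals; open triangles mark the upper limit that 0 UMIs allow (3 counts). In each class and gene shown, KrasG12D/+ lies below WT.

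The highest genes of the KrasG12D/+ library included Fn1, which leads a monocyte-like cluster, Naaa and Ckb, which lead the dendritic-like cluster, and Klf2, which was higher in many classes. Fn1, fibronectin (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200), stood at 21 against 2.23 CPM, a ratio of 9.40 [8.27 to 10.7]. Klf2, a transcription factor of quiescence and trafficking (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), stood at 976 against 154 CPM, a ratio of 6.36 [6.26 to 6.46]. Ckb, a creatine kinase, had a ratio of 7.60 [7.01 to 8.26], Naaa, a lysosomal lipid amidase, 5.76, Fbp1, an enzyme of gluconeogenesis, 5.40 [4.92 to 5.94], and BC100530, a stefin-like protease inhibitor of a near-identical family, 6.08 [5.70 to 6.49]. S100a6, a calcium-binding protein, stood at 1531 against 355 CPM, a ratio of 4.31 [4.27 to 4.36]. It is among the leading genes of maturing neutrophil-like cluster 10, which held 333 KrasG12D/+ and 34 WT cells.

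MHC class II genes, which present peptides to CD4 T cells, were higher in the whole library and lower in 5 of the 7 classes with a list median. In whole libraries 5 of 6 measured members were higher and none lower (6 with TMM), with a list median of 2.56. Cd74, the class II invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), stood at 1240.5 against 235 CPM (ratio 5.29 [5.22 to 5.36]), H2-Aa at 565 against 115 CPM (4.93 [4.84 to 5.02]) and H2-Eb1 at 352 against 75 CPM (4.69 [4.59 to 4.80]). With both libraries weighted to the WT class shares these directions turned, with ratios of 0.861 for Cd74, 0.781 for H2-Aa and 0.745 for H2-Eb1, and the list median became -0.09. Within dendritic-like cells, whose cluster these genes lead, 5 of 10 members were higher (8 with TMM; median 0.98). The list was lower in B lineage-like (5 of 6 members, median -1.98), HSC/MPP-like (5 of 7, -1.94), early erythroid-like (4 of 4, -1.81), lymphoid progenitor-like (8 of 8, -1.65) and monocyte-like cells (4 of 6, -0.997), and near the all-gene median in basophil/mast-like cells (-0.07). In monocyte-like cells Cd74 was found in 240 of 898 KrasG12D/+ and 140 of 689 WT cells, with 1556 and 3816 UMIs, so the lower level there rests on a minority of the WT cells. The 3 other classes had at most 2 measured members and no list median.

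The medians of the immediate early and Ras/MAPK output lists lay above the all-gene median, with members on both sides of WT. Of 14 immediate early and dissociation response genes, 6 were higher and 2 lower (11 and 1 with TMM), with a list median of 0.84 (0.35 with the mean of per-cell CPM). Atf3, a stress-induced transcription factor, stood at 49.6 against 14.1 CPM (ratio 3.52 [3.34 to 3.72]), Fos at 566 against 258 CPM (2.19 [2.16 to 2.22]) and Jun at 473 against 231 CPM (2.05 [2.02 to 2.08]). The heat-shock chaperone genes of this list went the other way, with Hsp90aa1 at 0.408 and Hspa8 at 0.550 of the WT level. Of 6 Ras/MAPK output genes, 3 were higher and 2 lower (4 and 0 with TMM; median 0.96). Dusp6, a phosphatase that limits ERK, had a ratio of 1.76 [1.67 to 1.85] and Ier3, an ERK-induced survival gene, 1.72 [1.65 to 1.79], while Myc had 0.588 and Spred1, a Ras inhibitor, 0.620.

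Within classes, the immediate early list median was highest in monocyte-like (1.40, 12 of 16 higher), neutrophil progenitor-like (1.38, 9 of 12) and dendritic-like cells (1.30, 12 of 15; with TMM 12, 10 and 13 were higher), and lowest in lymphoid progenitor-like cells (0.12). Egr1, an immediate early transcription factor induced by ERK, was 15.8-fold higher [11.2 to 23.1] in neutrophil progenitor-like cells, at 22.5 against 1.42 CPM, and 7.21-fold higher [5.89 to 8.90] in monocyte-like cells. Jun was 5.59-fold higher [5.33 to 5.87] in maturing neutrophil-like cells. The Ras/MAPK output median was 1.53 in monocyte-like, 1.31 in maturing neutrophil-like, 1.22 in early erythroid-like and 1.07 in neutrophil progenitor-like cells. In each of these classes only 1 of its Dusp, Spry, Spred and Etv feedback genes was measured. Those medians therefore rest mostly on other members of the list. The median was 0.85 in HSC/MPP-like and -0.28 in lymphoid progenitor-like cells, each with 5 of the feedback genes measured. Ccnd1, the cyclin that drives entry into S phase, stood at 42.8 against 1.66 CPM in early erythroid-like cells, a ratio of 25.8 [18.9 to 36.2], and 2.36-fold higher [1.82 to 3.04] in HSC/MPP-like cells. Ier3 was higher by 2.07 to 2.61-fold and Rhob, a small GTPase, by 1.95 to 3.02-fold in the 6 classes with at least 100 cells per library.

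The lists of Ras pathway parts and cytokine signalling moved little beyond the all-gene median. Of 16 Ras pathway components, 6 were lower and none higher (0 lower and 1 higher with TMM; median -0.13), with Ptpn11, a phosphatase mutated in this leukaemia, at 0.521 and Rasa1 at 0.569 of WT. Of 11 GM-CSF/IL-3 receptor and JAK-STAT genes, 7 were lower (1 lower and 2 higher with TMM; median -0.26), with Stat5a at 0.491 and Stat5b at 0.509, while the receptor chain Csf2ra had a ratio of 1.45. Of 13 inflammatory mediators and NF-kB targets, 3 were higher and 1 lower (7 and 1 with TMM; median 0.56). Cd14, a receptor for bacterial lipopolysaccharide, had a ratio of 2.30 and Cxcl2 1.76, whereas Il1b stood at 15.1 against 44.6 CPM (0.338). The cluster without a class held 784 of the 1878 KrasG12D/+ and 4766 of the 5253 WT UMIs of Il1b, so this ratio rests on few cells.

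Glycolysis genes stood above the all-gene median. Of 16 members 3 were higher and 2 lower (11 and 1 with TMM), with a list median of 0.74 and medians of 0.29 to 1.00 in the 10 classes. Eno1 had a ratio of 2.12 [2.07 to 2.16] and Pkm, pyruvate kinase, 1.56 [1.54 to 1.57], whereas the hexokinases Hk1 and Hk3 had 0.431 and 0.568. Oxidative phosphorylation genes of the nucleus (72 members, 2 lower, 4 higher with TMM) had a median of 0.30, at percentile 47.7 of the matched random lists, and -0.07 from genes matched on transcript length and expression. Ribosomal protein genes (82 members, 3 lower, 16 higher with TMM) had a median of 0.40, at percentile 53.6, and mitochondrial genes (11 members, 6 lower; 1 higher and 1 lower with TMM) a median of -0.21.

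In the lists of biosynthesis and stress response, no member was higher with library totals as scale, and the medians lay within 1.5-fold of the all-gene median. Of 24 Myc targets and ribosome biogenesis genes, 13 were lower (4 with TMM; median -0.28, percentile 0.120), led by Cad (0.342) and Polr1b (0.349). With both libraries at the WT class shares this list median turned to 0.06. Of 11 cholesterol and fatty acid synthesis genes, 6 were lower (3 with TMM; median -0.30, percentile 13.1), led by Fasn (0.336) and Scd2 (0.339). Of 13 genes of the unfolded protein and integrated stress response, 6 were lower (0 with TMM; median -0.12, percentile 2.59), among them the chaperones Canx (0.498) and Hsp90b1 (0.533). Of 11 antioxidant genes, 5 were lower (3 lower and 1 higher with TMM; median -0.02, percentile 14.1), with Gclc at 0.456 and Sod1 at 0.469. These medians depend on the reference: from genes matched on transcript length and expression they lay -0.46 for Myc targets, -0.09 for cholesterol and fatty acid synthesis, -0.37 for the unfolded protein response and -0.32 for antioxidant genes.

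The medians of the cell cycle, p53 and apoptosis lists lay within 1.5-fold of the all-gene median. Their counts of lower genes with library totals are therefore not read as a change of these lists. Of 43 S phase genes, 23 were lower (4 lower and 2 higher with TMM; median -0.22), with the replication helicase gene Mcm2 at 0.434 and Pola1 at 0.450. Of 49 G2/M genes, 17 were lower (1 lower and 3 higher with TMM; median -0.04). Of 14 cell cycle inhibitors and quiescence genes, 2 were higher and 4 lower (5 and 1 with TMM; median 0.01), with Gadd45g at 1.84 and Foxo3 at 0.399. Of 6 p53 targets, 1 was higher and 1 lower (1 and 0 with TMM; median 0.10): Pmaip1, which promotes apoptosis, had a ratio of 3.73 and Ccng1 of 0.521. Of 11 apoptosis regulators, 5 were lower (1 lower and 1 higher with TMM; median -0.16), led by Bcl2l11 (0.461).

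Of 14 iron and haem synthesis genes, 11 were lower (4 lower and 1 higher with TMM; median -0.49), with Cpox at 56.3 against 174 CPM (0.324). Of 18 haematopoietic transcription factors, 1 was higher and 10 lower (5 and 7 with TMM; median -0.39). The erythroid and megakaryocytic factors Zfpm1 (0.210), Tal1 (0.211) and Gata1 (0.226) were lower, Id2 was higher (2.24), and the myeloid factor Spi1 had a ratio of 1.45. Of 9 growth factor receptors, 4 were lower (1 lower and 3 higher with TMM; median 0.22), led by the erythropoietin receptor Epor (0.287). Of 14 adhesion and homing genes, 2 were higher and 5 lower (3 and 1 with TMM; median -0.07), with Cd63 at 1.88 and the integrin Itga4 at 0.484. Of 12 epigenetic regulators mutated in myeloid neoplasia, 8 were lower (2 with TMM; median -0.37), led by Dnmt3a (0.390) and Kmt2a (0.391). This list is long, at a median of 6458 nucleotides against 3244.5 over all genes, and its median lay -0.11 from genes matched on transcript length and expression.

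Marker lists in the whole libraries gave medians of 2.63 for dendritic cells, 0.94 for neutrophil progenitors, 0.92 for maturing neutrophils, 0.87 for monocytes and 0.13 for basophils and mast cells. The medians were -0.20 for lymphoid progenitors, -0.86 for macrophages, -0.99 for megakaryocyte-erythroid progenitors, -1.29 for late erythroid cells, -1.34 for early erythroid cells, -1.39 for B lineage cells, -1.56 for HSC/MPP and -2.42 for plasma cells. The marker lists of T/NK cells, megakaryocytes, eosinophils and stroma/endothelium had at most 2 measured members and got no median.

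**Figure D3:**
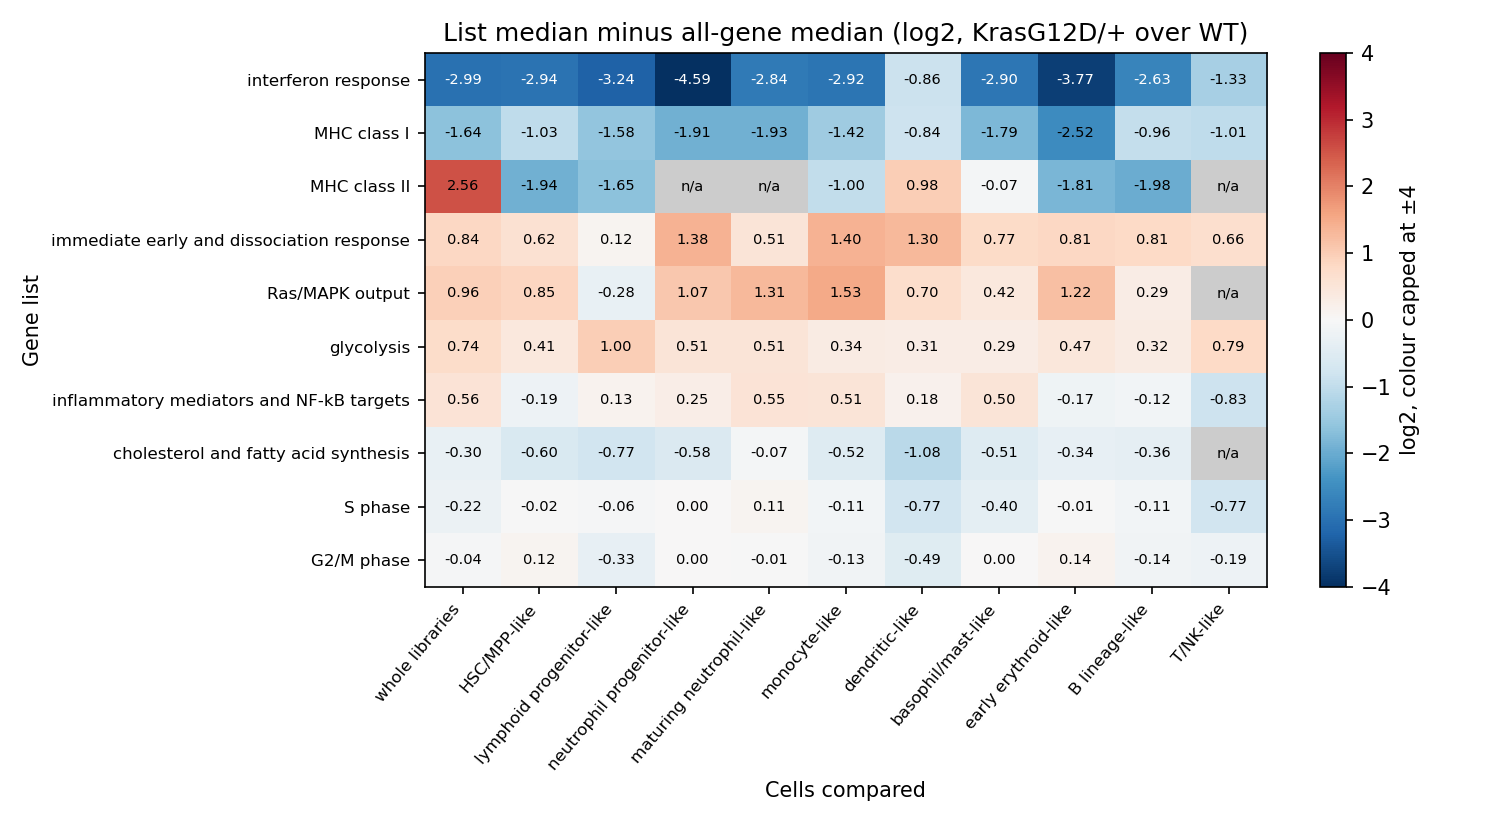
Median log2 ratio (KrasG12D/+ over WT) of 10 fixed gene lists minus the all-gene median, in the whole libraries and in 10 cell classes; grey cells had too few measured genes. The interferon response row runs from -0.86 to -4.59, and MHC class II is 2.56 in the whole libraries against -1.98 in B lineage-like cells.

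In maturing neutrophil-like and monocyte-like cells the levels of single genes moved both ways. Klf2 was 4.94-fold higher in maturing neutrophil-like and 4.71-fold higher [4.56 to 4.87] in monocyte-like cells. In maturing neutrophil-like cells Ccl3, a chemokine that draws in leukocytes, was 8.58-fold higher [6.67 to 11.2], H1f0, a linker histone, 6.29-fold and Stfa2, of a near-identical stefin family, 3.80-fold. In monocyte-like cells Hspa1b, an inducible heat-shock gene, stood at 0.159 against 25.6 CPM, a ratio of 0.00623 [0.00128 to 0.0183] from 3 UMIs, and Lrmda was 36.3-fold higher [21 to 68.7]. Different clusters held these classes in the libraries: monocyte-like clusters 2 and 8 were mostly KrasG12D/+ and 26 mostly WT, and maturing neutrophil-like clusters 1, 6 and 10 were mostly KrasG12D/+, 7 and 18 mostly WT and 11 mixed. Free RNA and mixed cells were not separated from these levels: S100a8, a gene abundant in neutrophils, stood at 7533 against 1295 CPM in monocyte-like cells. Camp, Ngp and S100a9 were also higher there (6.81, 6.76 and 5.92-fold).

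In neutrophil progenitor-like cells, held by clusters 3 and 5 in KrasG12D/+ and 24 and 27 in WT, Klf2 stood at 652 against 57.0 CPM, 11.4-fold higher [10.8 to 12.1]. S100a6 was 6.98-fold higher and Lrmda 15-fold higher. Beside the interferon genes Gbp2 (194-fold lower) and Rtp4 (93.8-fold lower), Gbp5 was 185-fold and Serpina3g 115-fold lower.

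HSC/MPP-like cells numbered 56 in KrasG12D/+ and 436 in WT. Their lowest genes were interferon-induced, with Igtp 44.2-fold lower and, from 1 to 3 UMIs in KrasG12D/+, ratios of 0.0203 [0.00417 to 0.0594] for Serpina3f, 0.0235 [0.000592 to 0.132] for Tgtp2, 0.0273 [0.0033 to 0.0992] for Zbp1 and 0.0334 [0.000841 to 0.188] for the chemokine gene Ccl5. Egr1 was 1.996-fold higher [1.75 to 2.27] and Ier3 2.52-fold higher [2.25 to 2.81]. The highest genes of this class, Ngp (18.5-fold), Ifitm6 (18.1-fold), Lcn2 (15.8-fold), Cd177 (15.8-fold) and Lgals3 (15.7-fold), include neutrophil granule genes. S100a8 stood at 17242 against 1264 CPM in the same cells.

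Early erythroid-like cells of the KrasG12D/+ library were higher for Ccnd1 and for 3 of 15 iron and haem synthesis genes. The libraries filled the clusters 9, 20 and 23 of this class unlike each other, with 80, 141 and 59 KrasG12D/+ and 299, 241 and 453 WT cells, so these levels compare differing mixtures. At resolution 2 the class held clusters with 58 KrasG12D/+ and 0 WT cells and with 2 and 453. No iron and haem synthesis gene was lower (median 0.37), with Alas2, the erythroid enzyme that starts haem synthesis, 2.34-fold higher [1.92 to 2.85] and the transferrin receptor Tfrc 1.62-fold higher [1.57 to 1.68]. Klf2 was 18.0-fold higher [14.7 to 22.1], while Zbp1, a sensor of viral nucleic acid, had a ratio of 0.00323 [0.000666 to 0.00946] from 3 UMIs. S100a6 was 20.5-fold higher. It is among the leading genes of a maturing neutrophil-like cluster, and free RNA and mixed cells were not separated from its level. Elane (22.1-fold), Ctsg (17.1-fold) and Slpi (16.2-fold), made by neutrophil progenitors and neutrophils, were also higher, where S100a8 stood at 6577 against 806 CPM.

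Dendritic-like cells of the KrasG12D/+ library were lower for proliferation and sterol synthesis genes. There 34 of 37 S phase genes (25 with TMM; median -0.77), 37 of 48 G2/M genes (19 with TMM; median -0.49) and 16 of 17 cholesterol and fatty acid synthesis genes (15 with TMM; median -1.08) were lower. Mki67, a proliferation marker, stood at 185 against 506 CPM (ratio 0.366 [0.329 to 0.409]), and Dhcr24, an enzyme of cholesterol synthesis, was 7.08-fold lower. Il1b was 3.97-fold higher [2.601 to 6.37], Il18 8.19-fold [2.76 to 40.03], Socs3, a feedback inhibitor of cytokine signalling, 11.0-fold [5.31 to 27.5] and Dusp6 28.6-fold [5.08 to 1134]. Fgfr1 (23.7-fold [9.23 to 87.2]) and Hepacam2 (21.9-fold [6.01 to 181]) were also higher, and Prg2, an eosinophil and basophil granule gene, was 93.5-fold lower. The class held 685 and 79 cells. At resolution 2 its libraries lay in different clusters, so these levels compare differing mixtures: the WT cells lay mostly in a cluster with Itgb7 and Batf3 (61 of 80, beside 233 KrasG12D/+ cells), and the KrasG12D/+ cells also in one with Xcr1 (324 against 10) and in one at a median of 2269 UMIs (132 against 9).

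Lymphoid progenitor-like cells, a cluster led by lymphoid genes and by the plasmacytoid dendritic cell genes Siglech and Cox6a2, were higher for 11 of 14 glycolysis genes. The KrasG12D/+ cells of this class depend on the setting: 306 in the setting reported and 276 without the filter on cells, but 133, 147, 151, 189 and 195 in 5 others, against 177 to 187 in WT. Their median was 21004 UMIs against 13323 in WT. Gene levels of this class are therefore not firm. Of 23 Myc targets and ribosome biogenesis genes 5 were higher (17 with TMM; median 0.66), among them Srm (2.13-fold [1.87 to 2.42]), and the glycolysis median was 1.00, with Eno1 (2.502-fold [2.13 to 2.95]). All 17 cholesterol and fatty acid synthesis genes were lower (12 with TMM; median -0.77), and cell cycle inhibitors and quiescence genes had a median of -0.72. Tacstd2, a surface glycoprotein, was 29-fold higher [7.89 to 242], Ccl9 6.90-fold higher [5.26 to 9.24], Cd74 25.1-fold lower and Ly6a 51.2-fold lower.

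In B lineage-like cells (91 and 336) Iigp1 was 109-fold, Igtp 54.2-fold, and Ly6a 37.4-fold lower, Isg15, from 1 UMI in KrasG12D/+, had a ratio of 0.0316 [0.000795 to 0.18], and Gbp4, at 0 UMIs against 179 CPM, was at least 41.5-fold lower. T/NK-like cells (72 and 71) were lower for Gzmb, the granzyme of cytotoxic granules (28.4 against 370 CPM, 13-fold), for Tnfrsf9, an activation receptor (10.4-fold), and for Stat1 (8.73-fold). Of 17 S phase genes 14 were lower there (11 with TMM, median -0.77). With classes from WT alone the T/NK-like class held 34 KrasG12D/+ and 55 WT cells, so these levels may compare differing mixtures. The highest genes of both classes were neutrophil progenitor genes: Elane was 12.7-fold higher in B lineage-like and 145-fold higher in T/NK-like cells (5393 against 37.1 CPM), where S100a8 stood at 6620.5 against 980.2 CPM and at 38637 against 1877 CPM. Basophil/mast-like cells were higher for Klf2 (19.3-fold), and for S100a6 (10.5-fold) and the neutrophil gene Retnlg (37.2-fold). S100a6 is among the leading genes of a maturing neutrophil-like cluster. The basophil/mast-like cells were lower for Iigp1 (at least 79.8-fold), Irgm1 (28.6-fold) and Gbp2 (ratio 0.017 [0.00348 to 0.0505] from 3 UMIs).

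Some genes were higher in each of the 6 classes with at least 100 cells per library. Cirbp, an RNA-binding protein induced by mild cold, was higher by 2.17 to 3.43-fold, Klf2 by 1.94 to 19.3-fold and the histone gene Hist1h2ap, one of a near-identical family, by 2.14 to 3.47-fold. Hist1h2bj (1.97 to 2.93-fold, 5 classes), Snx14 (2.48 to 3.61-fold, 3 classes) and Syngr1 (2.27 to 2.91-fold, 3 classes) were higher in each class where they were over the floor. Long transcripts stood lower in the KrasG12D/+ library: the median log2 ratio of all genes ran from -0.06 at a median length of 907 nucleotides to -0.77 at 8303 nucleotides, and the longest genes lay below the shortest in each class, by a difference of -0.30 to -1.11. From genes matched on transcript length and expression, the list medians were -3.09 for the interferon response, -1.92 for MHC class I, 2.15 for MHC class II, 0.73 for immediate early genes, 0.99 for Ras/MAPK output, 0.53 for glycolysis and 0.31 for inflammatory mediators.

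At equal depth, 20.6% of the KrasG12D/+ and 15.3% of the WT cells were called G1, 16.2% and 22.5% S, and 63.2% and 62.2% G2/M. Maturing neutrophil-like cells were called G2/M at 67.0% and 63.9%. Mature neutrophils divide little, but this class also holds cluster 6, with the neutrophil progenitor markers Fcnb and Cebpe among its leading genes. The calls were not checked against another measure of division, so they are not read as cycling. Median pseudotime along the joint map was 0.252 in KrasG12D/+ and 0.266 in WT cells. The pseudotime quartile ranges set by the WT cells held, from first to last, 19.3%, 41.8%, 27.4% and 11.6% of the KrasG12D/+ cells, and no direction is read since depth differed between the libraries.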

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

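The tests of class mix and of selection purity were chosen after the results were seen. Intervals over genes in the interferon gamma test and cold-induced genes in the handling test were not part of the rules set beforehand. The purity test was changed after 2 versions, which rested on the lymphoid progenitor-like class (reversed with other settings) and on the macrophage-like class (other cells when thinned).

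Interferon response and MHC class I genes were lower in the KrasG12D/+ library. Several technical explanations were argued against: the list stood at -0.86 or further below the all-gene median in each of the 10 classes, so class mix alone does not give it, and WT early erythroid-like cells held 108 times [101 to 127, over the members] the level that free RNA would carry over. The members' median lay -2.16 [-3.56 to -1.67] from genes matched on transcript length and expression, which argues against the length trend. The 31 members at least 2-fold lower lay on 15 chromosomes. For the set this argues against strain variants in the genes themselves within a few linked regions. The count cannot speak to a variant elsewhere that acts on all of these members. For the 10 of them on chromosome 17 this count of chromosomes cannot decide, since they share a chromosome. Exposure of the WT animal or animals, or of the suspension, mainly to interferon gamma stays open. Gamma-induced genes lay at least 2-fold below type I-induced genes in 2 of the 7 classes with enough genes of both, and below them in 6. In whole libraries the difference was -1.09 [-2.54 to 0.60]. The rule set beforehand counts such an outcome against this explanation, but the intervals over genes are too wide to decide. With 1 library per group the genotype cannot be told apart from a difference between the animals or suspensions. An example is an infection or inflammation in the WT animal or animals, whose number is not given. Any effect of the Kras allele on interferon signalling may therefore be raised only as an untested hypothesis.

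The dendritic-like class was larger and the HSC/MPP-like, megakaryocyte-like, early erythroid-like and B lineage-like classes were smaller in the KrasG12D/+ library. Counted without neutrophil, monocyte, dendritic and unnamed cells, early erythroid-like (0.728) and B lineage-like (0.699) ratios fell short of 1.5-fold. The HSC/MPP-like (0.331) and megakaryocyte-like (0.424) ratios did not. The 118 genes left out of the clustering as different between the libraries were argued against. Without them the HSC/MPP-like ratio was 0.167 [0.127 to 0.216] and the dendritic-like ratio 9.38. Other such genes stay open, since neutrophil progenitor-like clusters still split by library, with 730 against 17 and 20 against 821 cells. A difference in the purity of the c-Kit selection as the only cause would move classes with little Kit alike. Yet the maturing neutrophil-like ratio was 3.84 times the B lineage-like ratio, and 3.48 to 4.63 times over 10 settings. Its range of 2.88 to 5.17 divides opposite ends of both intervals and is not an exact interval. Both shares were known when this comparison was chosen, so it is no independent test. WT Kit stood at 17.6 CPM in maturing neutrophil-like and 26.7 CPM in B lineage-like cells, so these classes were not equally poor in Kit. The maturing neutrophil-like ratio was 5.49 times the macrophage-like ratio, and at least 4.50 times in other settings. When thinned it was 0.449 times that ratio, where the macrophage-like class holds other cells. A part played by purity stays open. The genotype also stays open with 1 library per group, and cannot be told apart from the animals or the suspension.

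The immediate early list median lay above the all-gene median, with 6 of 14 genes higher, and its heat-shock genes Hsp90aa1 and Hspa8 were lower in the KrasG12D/+ library. Temperature or handling of the suspension stays open, since it is confounded with the library. Heat-shock genes outside the lists lay at least 1.5-fold below the all-gene median in 1 of 10 classes, but below it in 8 (-0.60 to 0.14). By the rule set beforehand this outcome counts against handling. The bound of 1.5-fold in that rule was judged too far afterwards, since Hspa8, a gene of the pattern, itself lay only -0.46 from that median. The cold-induced genes Cirbp (1.93 to 3.43-fold) and Rbm3 (1.36 to 2.57-fold) were higher in all 10 classes, but that rule did not include them. Cirbp was named because it was higher across classes, so its level is no separate support for handling. Ras output alone as a cause stays open, since feedback genes of the Ras pathway lay more than 1.5-fold below the immediate early genes in 3 of 6 classes with enough genes, and the genotype itself was not tested, for lack of another library.

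The other results stand out because the libraries differ in opposite directions in a pair of classes; none of these differences was tested. MHC class II list medians were 0.98 in dendritic-like and -1.98 in B lineage-like cells, 2.96 apart on the log2 scale. The cell cycle inhibitors and quiescence list stood at 0.59 in basophil/mast-like and -0.72 in lymphoid progenitor-like cells, 1.31 apart. Elane was 145-fold higher in T/NK-like cells and at 0.328 of WT in HSC/MPP-like cells, 8.79 apart on the log2 scale. Cd177 was 15.8-fold higher in HSC/MPP-like cells and at 0.357 in dendritic-like cells, 5.47 apart. Fcnb was 36.1-fold higher [12.1 to 178] in T/NK-like cells and at 0.436 in dendritic-like cells, 6.37 apart. Retnlg was 37.2-fold higher in basophil/mast-like cells and at 0.139 in dendritic-like cells, 8.07 apart. These 4 genes are made by neutrophils or their progenitors, and free RNA and mixed cells were not separated from them: S100a8, another such gene, stood at 38637 against 1877 CPM in T/NK-like and at 3805 against 5038 CPM in dendritic-like cells. Cd74 was 1.77-fold higher in dendritic-like cells, whose cluster it leads, and at 0.0399 in lymphoid progenitor-like cells, 5.47 apart. H2-Eb1, which leads the same cluster, was 2.095-fold higher and at 0.0315 in those classes, 6.06 apart. Prg2, which leads the basophil/mast-like cluster, was 2.45-fold higher there and at 0.0107 in dendritic-like cells, 7.84 apart. Ccl3 was 8.58-fold higher in maturing neutrophil-like cells and at 0.393 in T/NK-like cells, 4.45 apart.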

How the results depend on the processing

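Chosen after the results were seen were the clustering without genes that differ between the libraries, the other denominator, the classes of at least 50 cells and the list medians taken from genes matched on transcript length and expression. Values are ratios of KrasG12D/+ over WT unless named otherwise. Of 138 class shares under alternatives, 87 stayed within their interval, 41 moved beyond it and 10 reversed. For 909 list medians these counts were 883, 22 and 4; for 806 named genes 527, 272 and 7; for 37 all-gene medians 14, 14 and 9; for 9 phase ratios 5, 3 and 1; for 8 pseudotime shares 5 and 3 with none reversed. The 1.08 ratio of maturing neutrophil-like cells, the directions of lymphoid progenitor-like and monocyte-like cells and the late erythroid-like ratio with the other denominator are not firm. The HSC/MPP-like class was not named at resolution 0.5, from WT cells alone or with thinned cells, nor megakaryocyte-like and lymphoid progenitor-like cells at 0.5, monocyte-like cells from WT alone, or plasma cell-like and stroma/endothelium-like cells when thinned. For the values below the cause was not tested, except that a change of scale or denominator moves values by construction.

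Some of these classes hold other cells than in the setting reported. The clusters named lymphoid progenitor in thinned cells and from WT alone scored best for HSC/MPP. The thinned dendritic-like class also holds a cluster that scored best for lymphoid progenitors, and the thinned macrophage-like class a cluster led by Fn1 and S100a4 beside C1q genes. The dendritic-like class at resolution 0.5 pools a cluster that scored best for HSC/MPP. Thinned cells gave ratios of 2.22 for dendritic-like, 0.353 for early erythroid-like, 0.150 for lymphoid progenitor-like, 2.40 for macrophage-like, 0.0396 for megakaryocyte-like, 1.16 for monocyte-like, 0.479 for T/NK-like and 0.673 for basophil/mast-like cells. Classes from WT cells alone gave 4.01 for dendritic-like, 0.246 for lymphoid progenitor-like, 0.105 for megakaryocyte-like and 0.640 for T/NK-like cells. Resolution 0.5 gave 1.49 for dendritic-like, 1.53 for monocyte-like and 0.475 for basophil/mast-like cells, whose cluster then scored best for megakaryocytes. Resolution 2 gave 0.192 for HSC/MPP-like, 1.07 for lymphoid progenitor-like, 0.983 for maturing neutrophil-like, 0.899 for monocyte-like and 1.98 for neutrophil progenitor-like cells. The stricter filter gave 0.204 for HSC/MPP-like, 0.744 for lymphoid progenitor-like, 1.16 for maturing neutrophil-like, 0.0666 for megakaryocyte-like, 1.51 for monocyte-like and 1.23 for neutrophil progenitor-like cells. No filter gave 1.20 for maturing neutrophil-like, 0.752 for plasma cell-like and 0.234 for late erythroid-like cells. Doublets kept gave 0.817 for lymphoid progenitor-like, 0.971 for maturing neutrophil-like, 1.69 for monocyte-like and 1.76 for neutrophil progenitor-like cells. Without cell cycle genes the ratios were 0.181 for HSC/MPP-like, 0.854 for lymphoid progenitor-like, 1.17 for maturing neutrophil-like and 1.32 for neutrophil progenitor-like cells. Without genes that differ between the libraries they were 1.08 for lymphoid progenitor-like and 1.01 for maturing neutrophil-like cells. The other denominator gave 0.699 for B lineage-like, 0.331 for HSC/MPP-like, 0.728 for early erythroid-like, 1.02 for late erythroid-like, 4.22 for lymphoid progenitor-like, 0.489 for macrophage-like, 0.424 for megakaryocyte-like, 2.62 for T/NK-like, 2.89 for basophil/mast-like, 1.72 for stroma/endothelium-like and 0.369 for plasma cell-like cells.

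TMM scaling gave all-gene median log2 ratios of 0.0739 in whole libraries, 0.0736 in T/NK-like, 0.0665 in dendritic-like, 0.0559 in basophil/mast-like, 0.0898 in lymphoid progenitor-like, 0.0405 in maturing neutrophil-like, 0.0187 in monocyte-like and 0.122 in neutrophil progenitor-like cells. It gave Hras 1.04 in whole libraries and 1.23 in neutrophil progenitor-like cells, and for the Hras ratio, monocyte-like cells gave 1.0035. Median-of-ratios scaling gave an all-gene median of 0.0292 and an Hras ratio of 1.02. Genes matched on transcript length and expression gave a nuclear oxidative phosphorylation list median of -0.0738 in whole libraries. The WT class shares gave an all-gene median of -0.23, list medians of -0.0945 for MHC class II and 0.0578 for Myc targets, and ratios of 0.861 for Cd74, 0.781 for H2-Aa and 0.745 for H2-Eb1. Mean per-cell CPM gave an all-gene median of -0.38, an immediate early list median of 0.35 and, for the nuclear oxidative phosphorylation list median minus all-gene median, basophil/mast-like cells gave -0.00786. Without haemoglobin, mitochondrial and ribosomal genes in the totals the all-gene median was -0.43. Cells at their own depth gave phase ratios of 0.973 for G1, 0.855 for S and 1.07 for G2/M. The ratio of G1 phase shares in the HSC/MPP-like and neutrophil progenitor-like classes was 0.399 with calls made within the pool of both, whose class mix differs between the libraries. Called within each class, G1 took 19.2% against 17.7% of the HSC/MPP-like and 1.503% against 1.15% of the neutrophil progenitor-like cells. Of the KrasG12D/+ cells 14.8% lay in the first and 22.5% in the last WT pseudotime quartile range with thinned cells, and 13.1% in the last with 15 principal components.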

Other observations

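The test of genes near Kras was fixed before its result was seen. Chemokine genes induced by interferon were found in few KrasG12D/+ cells. Cxcl9, which draws in T cells, stood at 2.44 CPM in the KrasG12D/+ and 11.6 CPM in the WT library. In WT it was highest in stroma/endothelium-like cells, whose cluster it leads (3219 CPM), and reached 121 CPM in macrophage-like cells. The 32 and 47 KrasG12D/+ cells of these classes had 0 UMIs, which allows up to 21.2 and 11.2 CPM, and 294 of the 304 KrasG12D/+ UMIs lay in dendritic-like cells, at 39.9 against 70.0 CPM. Cxcl10 stood at 2.62 against 19.5 CPM over all kept cells and at 12.3 against 70.7 CPM in HSC/MPP-like cells. It was level in maturing neutrophil-like cells, at 1.17 against 1.39 CPM, and went the other way in T/NK-like cells, at 35.9 [22.99 to 53.4] against 12.9 CPM [5.57 to 25.4], from 2 and 7 cells. The summed level of Ifng itself did not differ beyond counting error in T/NK-like cells, at 73.3 [54.2 to 96.9] against 77.5 CPM [57.1 to 103]. Its UMIs came from 16 of 72 KrasG12D/+ and 27 of 71 WT cells.

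The cluster left without a class name was led by inflammatory genes of neutrophils. It held different cells in each library: at resolution 2 a cluster led by stefin genes had 74 KrasG12D/+ and 2 WT cells, and one led by Il1b, Acod1 and Ptgs2 had 5 and 276, so gene levels are not compared within it. Over all kept cells Cd274, the checkpoint ligand PD-L1, stood at 2.13 against 12.7 CPM. Ciita, the activator of MHC class II genes, stood at 172 CPM in KrasG12D/+ and 207 CPM in WT dendritic-like cells and at 1.89 [0.229 to 6.84] against 17.3 CPM [14.2 to 20.7] in HSC/MPP-like cells.

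Sequence carried along beside the Kras allele could alter its neighbours on chromosome 6, and this was tested within 5 Mb of Kras. In neutrophil progenitor-like cells 21 genes had a median absolute log2 ratio of 0.38, at percentile 22.4 of random matched lists. In early erythroid-like cells 18 genes had one of 0.19, at percentile 38.1. Both argue against an effect on the region as a whole. Effects on single neighbours were not tested: Etnk1 was lower (ratios 0.281 and 0.497) and Etfrf1 higher (1.88 and 1.63) in these classes.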
